A study of Mus musculus with 6 samples.

How the data were processed

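RNA of 6 mouse testis samples, 3 Thy1-negative and 3 Thy1-positive, was measured on Affymetrix arrays that cover the mouse genome, 1 array per sample. The deposited table gives 1 intensity per probe set and array, on a linear scale. Per the labels the processing tool was GCRMA, with no version given, whereas the sample descriptions of the labels refer to the Affymetrix software with scaling to a target of 150 after trimming of 2%. The trimmed mean of the table is 287 to 293 on every array, so the values do not carry that scaling; which procedure made the table is not given in the sources used here. Detection calls were not used here.

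The table holds 45101 probe sets, of which 64 Affymetrix controls were left out of the tests, leaving 45037. Values were taken as log2(intensity + 1), with no further normalization and no filter. Gene symbols came from the supplied platform table: 34945 probe sets had 1 gene, 932 several and 9160 none. Symbols were checked against a supplied RefSeq gene table of the GRCm38.p6 assembly by Entrez identifier, which updated 0 symbols; 204 of the probe sets with 1 gene had no match. No coordinates were used. At gene level the probe set with the highest mean over the 6 arrays was kept for each of 18193 genes. A gene was said to be at low signal in a fraction where its mean was below the 25th percentile of the arrays. The fold of a named gene at low signal in 1 fraction is given as a bound, with values of that fraction below the 25th percentile of their array raised to it. This percentile lies near background itself, so the bound holds for that floor alone, and other settings can give smaller folds. Log2 differences are those measured.

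Thy1-positive and Thy1-negative arrays were compared with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) in a model with fraction as its single term, with 2-sided tests and Benjamini-Hochberg adjustment at 0.05 over all probe sets or all genes. The same preparation is not stated to underlie arrays of the same number, so no block was used in the reported values. A probe set at 10-fold or more had an adjusted p below 0.05 and a difference of mean log2 values of at least log2(10). SD is between the 3 arrays of a fraction and SE is that of limma.

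The choices above, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined, except where stated. The named genes were Thy1 and 16 others whatever their values; the 10 genes with the largest increase and the 10 with the largest decrease among called genes whose fractions did not overlap and whose probe set is not one that Affymetrix marks as cross-hybridising by the ending _x_at; and up to 3 members per direction with the largest called changes in each list. The rule gave 119 genes; 60 had several probe sets, of which 33 disagreed in call and 1 had probe sets called in opposite directions.

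The 25 lists were undifferentiated spermatogonia, differentiating spermatogonia, pan-germline genes (the genes shared by all germ cells), meiotic prophase, GDNF-responsive genes, pluripotency-associated genes, Sertoli cell, Leydig cell, peritubular myoid cell, interstitial mesenchyme, endothelium, macrophage, T lymphocyte, erythroid cell, niche factor receptors, niche ligands, integrins and cadherins, basement membrane and matrix, cell cycle and DNA replication, cholesterol biosynthesis, glycolysis, DNA methylation and chromatin, imprinted genes, immediate early and dissociation response genes, and housekeeping genes. Members without a probe set of their own, such as Nanos2 and Nanos3, were not analysed here. Several lists share members, so their results are not independent. Csf1r is in both the macrophage and the receptor list. Bcl6b, Etv5, Lhx1, Egr2, Tspan8 and Pou3f1 are in both the undifferentiated and the GDNF-responsive list. Gdnf, Kitl, Dhh, Inhbb and Fgf9 are in both the Sertoli and the ligand list. Other pairs of lists share genes too. A further 4 lists (cytotoxic lymphocyte, mast cell, MHC class I and II, and hormone-related genes of Sertoli and granulosa cells) were written after the values had been seen. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the lists. Counts of called members are given over all genes and adjusted over the list alone.

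The alternative settings were quantile normalization, centring of arrays on their median or on the housekeeping list, probe sets above the median only, low values raised to the 25th percentile (which drops probe sets that then equal it on all arrays), a pseudocount of 16, the replicate number as a block, an intensity trend with robust variance, array weights, leaving out each array, leaving out probe sets ending in _x_at or _s_at, and the mean of all probe sets of a gene. Leaving out both arrays numbered 2, or both numbered 3, was added after the data had been seen. Where an array was left out, the most abundant probe set per gene was chosen again.

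The tests were tried on simulated data with 45037 probe sets, of which 200 were changed in the comparison of 3 against 3 arrays. The changed probe sets were drawn from those above the median intensity. The share of changes recovered was 14% at 2-fold, 50% at 4-fold, 76% at 10-fold and 80% at 32-fold, with 0 of them called in the wrong direction by limma and 6 false calls. These shares do not describe dim probe sets, nor a comparison with as many changes as the real one, where 23.4% of probe sets were called. Of 500 random lists of 20 genes, 3.2% had a camera p below 0.05. The genes were simulated independently, so this rate does not cover lists whose genes are correlated. In the real data, 1 split that mixed the fractions called 15 of the 25 lists.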

Results

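RNA was measured in cell fractions of prepubertal mouse testis that had been separated by magnetic sorting for Thy1, a glycoprotein of the cell surface. Per the labels, transplantation assays placed more spermatogonial stem cells in the Thy1-positive fraction than in the Thy1-negative fraction. The comparison asks which genes are higher in that enriched fraction, with special attention to those at 10-fold or more. Each fraction has 3 arrays from independent donor preparations, called N1, N2 and N3 in the Thy1-negative and P1, P2 and P3 in the Thy1-positive fraction. The small number of arrays limits the precision of every value. Values are log2(intensity + 1), differences are Thy1-positive minus Thy1-negative, and adjusted p is from limma over 18193 genes, with n = 3 arrays per fraction throughout.

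The 6 arrays had median intensities between 15.7 and 17.5. The ratio of the 3' to the 5' control probe set of Actb lay between 1.82 and 2.33, and that of Gapdh between 0.736 and 1.04. The 5' control probe set of 18S ribosomal RNA measured 336, 29178 and 12545 on N1, N2 and N3 against 187, 33.7 and 47.6 on P1, P2 and P3. This ribosomal signal was not tested and varied most among the Thy1-negative arrays. The first principal component held 84.2% of the variance and parted the fractions, with N1, N2 and N3 at -119, -62.0 and -111 and P1, P2 and P3 at 107, 81.8 and 103. N2 was therefore the Thy1-negative array nearest to the Thy1-positive ones.

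The lists of undifferentiated spermatogonia, macrophages and germ cells in general were higher in Thy1-positive cells, and those of Sertoli and peritubular myoid cells lower, at a preset correlation between genes. None passed with an estimated correlation (adjusted p = 0.385, 0.356, 0.621, 0.459 and 0.426 in this order), and the higher genes of the germ cell list numbered 0 without N3 or P3. Thy1 itself measured 6.20 ± 0.27 (SD) in Thy1-positive and 2.48 ± 0.23 in Thy1-negative cells, where it was at low signal, and was at least 11.4-fold higher with adjusted p = 0.000984. Over the alternative settings its smallest log2 difference was 2.11. Gfra1 and Ret, which together form the receptor for GDNF, rose 11.1-fold (3.47, SE 0.10, adjusted p = 0.000168) and 12.3-fold (3.62, SE 0.24, adjusted p = 0.00193). The other probe sets of Gfra1 differed by 5.47 and 4.71, and that of Ret by 3.69. Among transcriptional regulators of spermatogonia, Bcl6b rose 10.4-fold (3.37, SE 0.07), Lhx1 12.8-fold (3.68, SE 0.29), Pou5f1 12.2-fold (3.61, SE 0.44) and Id4 6.68-fold (2.74, SE 0.18). The other probe sets of Id4 differed by 3.63 and 2.11. Etv5 rose 3.61-fold (1.85, SE 0.21, adjusted p = 0.00590) and Zbtb16, which encodes PLZF, 5.71-fold (2.51, SE 0.39, adjusted p = 0.0117). Csf1r, the receptor for the macrophage growth factor CSF1, rose 13.4-fold (3.74, SE 0.23), and its other probe sets differed by 8.63, from low signal in Thy1-negative cells (2.56), and 6.75.

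Gdnf, the growth factor that Sertoli cells supply to stem cells, was 24.8-fold lower in Thy1-positive cells (-4.63, SE 0.47, adjusted p = 0.00506). Sox9, a transcription factor of Sertoli cells, was 16.6-fold lower (-4.05, SE 0.61, adjusted p = 0.0112), while of its other probe sets 1 differed by -3.92 and 1 by -0.06. The latter was dim in both fractions (3.55 in Thy1-positive against 3.61 in Thy1-negative cells), so it says little. Itga6, an integrin subunit, was 1.60-fold lower (-0.67, SE 0.09). Ddx4, an RNA helicase of germ cells, rose 2.41-fold (1.27, SE 0.32, adjusted p = 0.0421), although its probe set did not pass when adjusted over all probe sets (adjusted p = 0.0552). In all, 11 named genes passed over genes but not over all probe sets. The others, named below, were Tcf21 (adjusted p = 0.0508), Sdha (0.0524), Hormad2 (0.0542), Ramp2 and Tpi1 (both 0.0548), Kdr (0.0574), Grb10 (0.0578), Sohlh1 (0.0590), Nr4a1 (0.0618) and Epcam (0.0626). Kit, the receptor of differentiating spermatogonia, did not differ detectably: it measured 9.91 ± 0.29 against 9.91 ± 1.03, with adjusted p = 1.00. Csf1 (-0.85, SE 0.59, adjusted p = 0.356) and Cyp11a1 (-0.81, SE 0.39, adjusted p = 0.191) did not pass. Among the 6 fits that left out 1 array, Ddx4 passed only without N2 (1.57) and Csf1 only without P2 (-1.46), and Zbtb16 and Sox9 failed without N3 (2.40 and -3.98) and without P3 (2.54 and -3.85). Leaving out N1, N2 or N3 made another probe set the most abundant for Csf1r, with differences of 8.63, 8.63 and 8.64 from low signal. Of the called named genes, 8 have another probe set above the median intensity that was not called and pointed the other way or differed by less than 0.5 times as much. For Zbtb16 it differed by 1.05, Bmpr2 by -0.44, Epcam by -0.04, Hmgcs1 by -0.11 and Grb10 by -0.17; Kif11, Cbx1 and Sdha are described below.

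**Figure D1:**
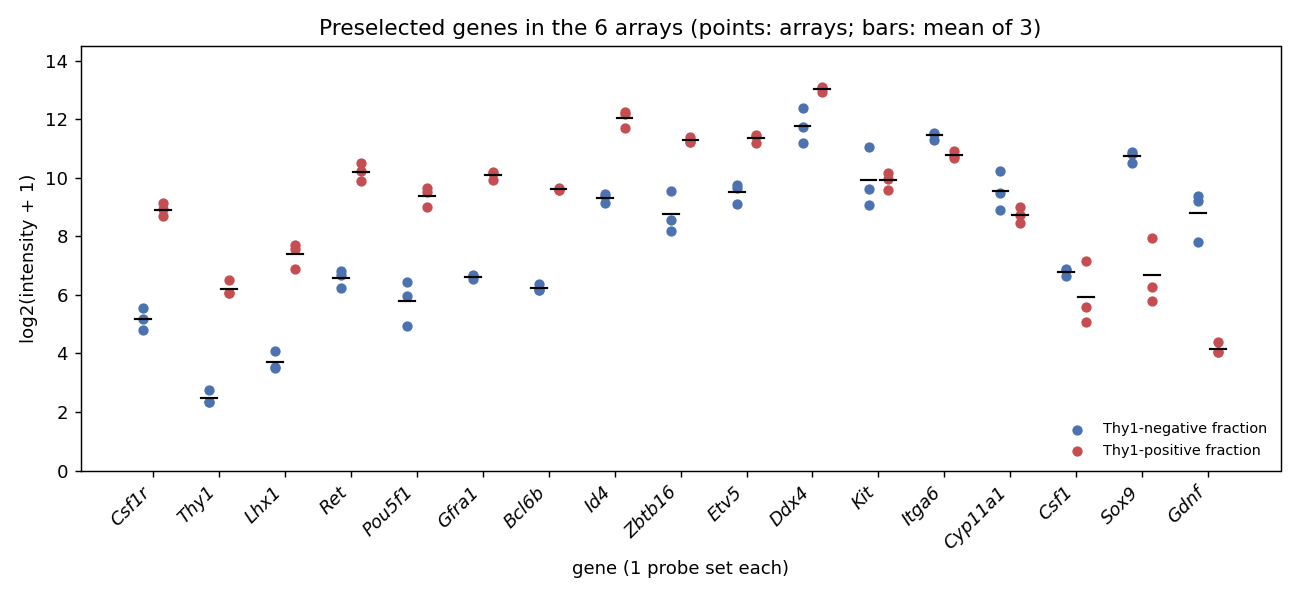
Log2(intensity + 1) of 17 genes fixed in advance, on each of the 3 Thy1-negative and 3 Thy1-positive arrays, with bars at the mean of 3 arrays. Thy1 lies at 2.48 against 6.20 and Gdnf at 8.80 against 4.16, while Kit has the mean 9.91 in both fractions.

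The 10 genes with the highest increases were taken by the probe set kept per gene, leaving out genes whose kept probe set ends in _x_at. Of these 10, 7 are in the macrophage list, all but Pf4, Ctsc and Ptprc. The macrophage genes C1qb (11.25 in Thy1-positive against 3.54 in Thy1-negative cells) and Laptm5 (11.06 against 3.69) were left out by that rule, although they rose more than Ptprc. Csf1r is not among the 10, although another of its probe sets differed by 8.63 from low signal. Pf4, a chemokine of platelets and macrophages, was at least 290-fold higher (8.26, SE 0.20), F13a1, a coagulation factor subunit, at least 243-fold (8.08, SE 0.33), and the complement genes C1qa and C1qc at least 195-fold (7.99, SE 0.13) and 125-fold (7.44, SE 0.22). The lysosomal proteases Ctss and Ctsc rose 225-fold and 152-fold, and the signalling adaptors Tyrobp and Fcer1g 203-fold and 107-fold. Lysozyme Lyz2 rose 143-fold and Ptprc, the leukocyte antigen CD45, at least 87.8-fold (6.63, SE 0.04, adjusted p = 2.96e-06). Pf4, F13a1, C1qa, C1qc and Ptprc were at low signal in Thy1-negative cells, so their folds are bounds and their order rests on values near background. Tyrobp (3.03, SD 0.01) and Ctsc (4.16, SD 0.01) were above that level in Thy1-negative cells but hardly varied there, and their folds share the limit. Under the same rule the genes with the strongest decreases were Cbln4 (53.4-fold lower; -5.74, SE 0.89), the Sertoli cell hormone Amh (at least 29.2-fold lower; -5.61, SE 0.55), Gpr37 (38.8-fold lower), Rarres1 (38.2-fold lower) and Dpysl4 (38.1-fold lower). They were followed by the FSH receptor Fshr (at least 26.9-fold lower; -5.14, SE 0.51), the peptide hormone precursor Edn1 (34.8-fold lower), Scara3 (33.1-fold lower), Plac1 (33.0-fold lower) and Exoc3l2 (32.5-fold lower). Amh and Fshr were at low signal in Thy1-positive cells, and Cbln4 (2.96, SD 0.05) lay just above that level and hardly varied there. Their folds and their place in this order, which is that of the measured differences, rest on values near background. Over the alternative settings the smallest decreases of Amh and Fshr were -3.44 and -3.36. The decrease of Gpr37 failed without P3 (-5.29), and that of Cbln4 without N3 (-5.43) or P3 (-5.74). Dpysl4 failed without N1 (-5.23), N3 (-5.24) or P3 (-5.12), and Exoc3l2 failed without N1 (-4.89), N3 (-4.94), P1 (-4.67) or P3 (-4.39).

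Of 45037 probe sets, 5332 were higher and 5201 lower in Thy1-positive cells at an adjusted p below 0.05, together 23.4% of those tested; 15784 had an unadjusted p below 0.05. At gene level, 3368 genes were higher and 2628 lower. The arrays of the fractions did not overlap for 9351 genes (51.4%), where chance gives 10%. At 10-fold or more, 191 probe sets were higher, naming 144 distinct genes besides 18 probe sets without a single gene. At the same fold 363 were lower, naming 238 genes besides 45 such probe sets. By fold alone the counts were 191 and 365. With 1 probe set per gene, 130 genes were at least 10-fold higher and 200 at least 10-fold lower. The counts by list took a gene if any of its probe sets passed at 10-fold or more, not only the probe set kept. On that basis 19 of the 21 listed macrophage genes and 9 of the 30 undifferentiated spermatogonia genes were higher. Of the 22 Sertoli cell genes, 19 were lower.

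Of the called probe sets, 50.6% were higher in Thy1-positive cells. The share was 81.4% with each array centred on its median and 38.8% with each array centred on housekeeping genes. The median difference of all genes was 0.01, 0.13 and -0.12 under these scalings. Centring shifts every probe set of an array alike, also the 36.7% to 37.3% per array that measured below 3. The shares can therefore move through dim probe sets that hardly vary, and which probe sets gained a call was not examined. At 10-fold or more, 219 were higher and 314 lower with median centring, and 168 and 433 with housekeeping centring. The counts of higher and lower probe sets dropped to 2806 and 2791 without N1, 2067 and 2161 without N3, 2657 and 2773 without P1 and 1639 and 1538 without P3. The lower 10-fold count dropped to 232, 181, 238 and 159 in the same order. With the replicate number of the labels as a block, 746 probe sets were higher and 485 lower. With low values raised to the 25th percentile the 10-fold counts were 186 and 357. A pseudocount of 16 left 72 higher and 192 lower probe sets at 10-fold or more. Alternatives chosen after seeing the data gave 6521 higher and 5738 lower probe sets without both arrays numbered 2, with 250 and 568 at 10-fold or more, and 219 and 144 without both arrays numbered 3, with 79 and 14.

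Among markers of undifferentiated spermatogonia, 20 of 30 rose and 3 fell, with 22 and 3 adjusted over the list alone and a median difference of 1.96. Besides the genes above, Tcl1, a coactivator of AKT signalling, rose 15.1-fold (3.92, SE 0.23). Those that fell were Shisa6 (-3.17, SE 0.28), the adhesion receptor Adgra3 (-2.45, SE 0.25) and the ephrin receptor Epha2 (-1.04, SE 0.24), which passed only without N2 among the leave-one-out fits (-1.28). As a set the list was higher than other genes (camera adjusted p = 6.85e-06; adjusted p = 0.385 with an estimated correlation). Without both arrays numbered 3, 4 rose. Macrophage genes rose in the same arrays, by a median of 6.10. Of genes that respond to GDNF, 6 of 12 rose, also 6 adjusted over the list alone, with a median of 1.62 (camera adjusted p = 0.00991; adjusted p = 0.615 with an estimated correlation and 0.190 with arrays centred on their median). Among them was the transcription factor Etv4 (2.93, SE 0.18), and 1 gene fell when N2 was left out. Bcl6b, Etv5, Lhx1, Egr2, Tspan8 and Pou3f1 of this list are also in the undifferentiated list, so these lists are not separate results. Of genes associated with pluripotency, 8 of 17 rose and 1 fell, with 9 and 1 adjusted over the list alone and a median of 0.97. The set did not pass (camera adjusted p = 0.0617; adjusted p = 0.459 with an estimated correlation). Dppa4 rose (2.98, SE 0.27) and Zfp42, known as Rex1, rose (2.87, SE 0.54), while the proto-oncogene Myc fell (-1.08, SE 0.26). Zfp42 and Myc passed only without N2 among the leave-one-out fits (3.45 and -1.35). The count of higher pluripotency genes was 4, 4, 5 and 4 without N1, N3, P2 and P3.

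Genes shared by all germ cells were higher in Thy1-positive cells by a mean of 1.73. Of 27 measured, 11 rose, or 17 adjusted over the list alone (camera adjusted p = 0.000124; adjusted p = 0.621 with an estimated correlation). They included Usp26 (2.59, SE 0.50) and Tdrd1 and Tdrd5 (2.57, SE 0.46; 2.49, SE 0.38), Tudor domain genes of the piRNA pathway. Of genes of differentiating spermatogonia, 4 of 13 rose, 5 adjusted over the list alone, with a median of 0.64. The set did not pass (camera adjusted p = 0.209; adjusted p = 0.810 with an estimated correlation). The transcription factor genes Sohlh1 (2.03, SE 0.53, adjusted p = 0.0590 over all probe sets) and Sohlh2 (1.82, SE 0.43) and the deubiquitinase gene Uchl1 (1.74, SE 0.37) rose. Membership of this list does not show that a gene is limited to differentiating cells. Of genes of meiotic prophase, 2 of 18 rose, 0 adjusted over the list alone by limma, with a median of 1.32 and a camera adjusted p of 0.0193 (adjusted p = 0.763 with an estimated correlation and 0.350 with arrays centred on their median); 9 had an unadjusted p below 0.05. The pair that rose was Hormad2 (1.10, SE 0.28), a protein of the meiotic chromosome axis, and 4930432K21Rik (1.59, SE 0.34), also known as Brme1. The list means of the Thy1-negative arrays N1, N2 and N3 were 8.33, 10.05 and 8.88 for the germ cell list and 6.26, 8.19 and 6.79 for the meiotic list. N2 lay nearest to the Thy1-positive means of 10.82 and 8.39. Without N1, N2, N3, P1, P2 and P3 in turn, the higher genes numbered 6, 25, 0, 1, 2 and 0 in the germ cell list, 0, 7, 0, 0, 0 and 0 in the differentiating list and 1, 15, 0, 0, 0 and 0 in the meiotic list. Of the genes named here Tdrd5 passed in 4 of those 6 fits, Usp26 and Tdrd1 in 2, and the rest in 1. The macrophage genes rose beside these lists, with all 21 called in each fit.

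**Figure D2:**
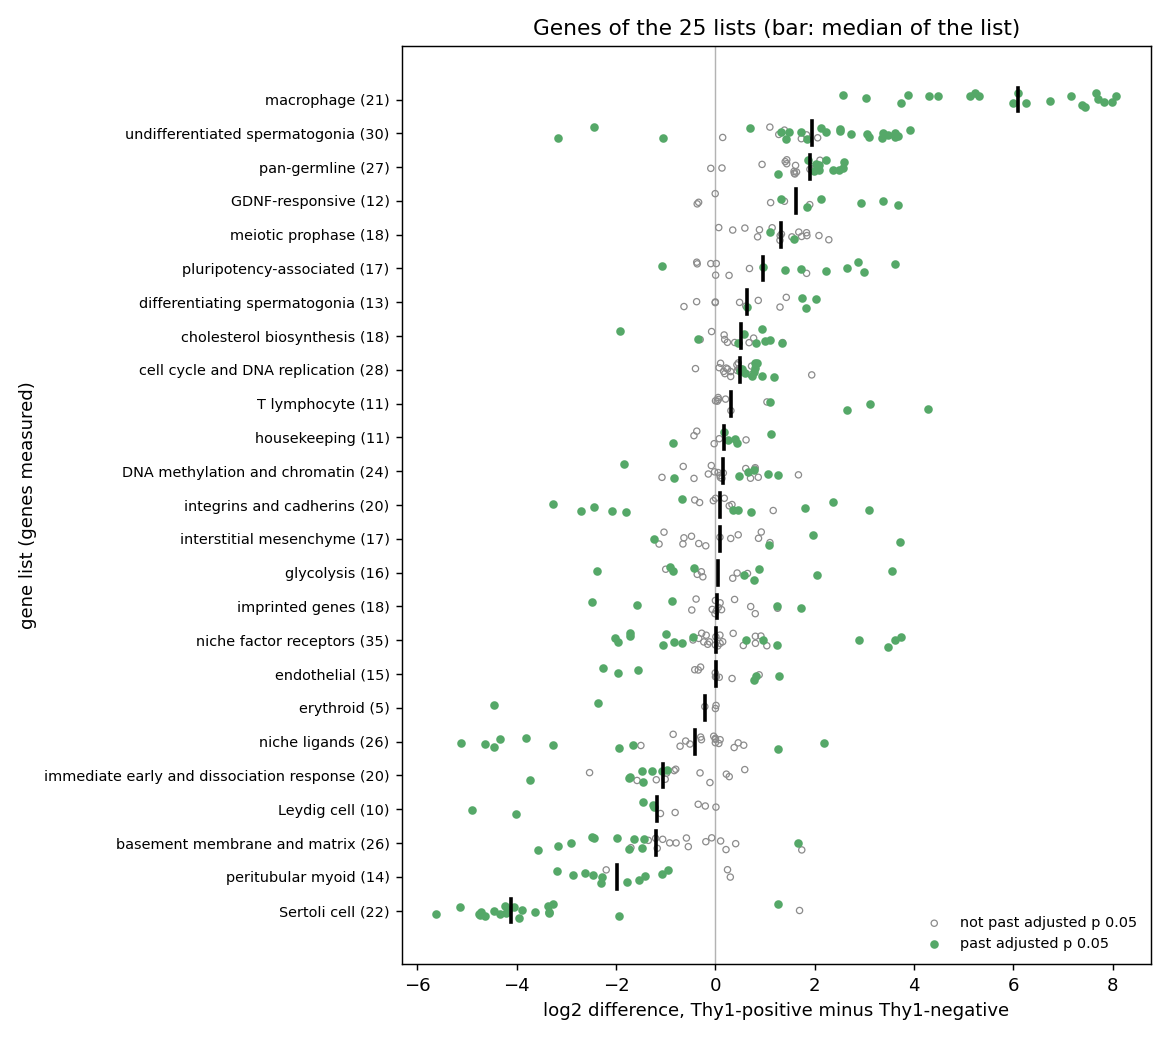
Log2 difference between Thy1-positive and Thy1-negative cells for each measured gene of 25 lists fixed in advance, filled where the adjusted p is below 0.05, with a bar at the list's median. The macrophage median lies at 6.10, the undifferentiated spermatogonia median at 1.96 and the Sertoli cell median at -4.11; under housekeeping centring the set test of the mesenchyme, endothelial, receptor, integrin, glycolysis and imprinted lists changes direction.

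All 21 macrophage genes were higher in Thy1-positive cells, also 21 adjusted over the list alone, with a median of 6.10 (camera adjusted p = 5.71e-18; adjusted p = 0.356 with an estimated correlation). Without both arrays numbered 3 the count was 11, and in each fit without 1 array it was 21. The list's mean was 9.33 ± 0.21 (SD) in Thy1-positive and 3.42 ± 0.08 in Thy1-negative cells, and 6 members were at low signal in the latter. Its members with the highest intensities in Thy1-positive cells were Lyz2 at 12.04, the complement gene C1qb at 11.25, the mannose receptor Mrc1 at 11.17, Laptm5 at 11.06 and Ctss at 11.00. Intensities of different probe sets do not rank the abundance of their genes. Of T lymphocyte genes, 4 of 11 rose, 5 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.00509; adjusted p = 0.385 with an estimated correlation). The CD3 subunit genes Cd3g and Cd3d rose by 4.28 (SE 0.06) and 2.66 (SE 0.30), Cd3d from low signal in Thy1-negative cells and Cd3g from just above it (2.74, SD 0.003), and the adaptor Lat by 3.11 (SE 0.21). Of 5 erythroid genes, 2 fell, also 2 adjusted over the list alone, with a median of -0.21. They were Alas2, an enzyme of haem synthesis (-4.46, SE 0.43, at low signal in Thy1-positive cells), and the anion exchanger Slc4a1 (-2.36, SE 0.24). Slc4a1 differed by -1.11, -1.35 and -1.04 without N1, N2 and N3, where another probe set was the most abundant. The erythroid set did not pass (camera adjusted p = 0.0617; adjusted p = 0.621 with an estimated correlation).

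Sertoli cell genes were lower in Thy1-positive cells by a median of -4.11. Of 22 measured, 20 fell and 1 rose, with 20 and 2 adjusted over the list alone (camera adjusted p = 4.26e-09; adjusted p = 0.459 with an estimated correlation). Besides Amh and Fshr, the prostaglandin synthase Ptgds fell (-4.76, SE 0.82), and the growth factor Fgf9 rose (1.26, SE 0.19). P2 had a Sertoli list mean of 8.10, against 6.69 on P1 and 6.82 on P3. Of peritubular myoid genes, 11 of 14 fell, 12 adjusted over the list alone, with a median of -1.99 (camera adjusted p = 1.01e-06; adjusted p = 0.426 with an estimated correlation). The contractile genes Myh11 (-3.19, SE 0.24), Acta2 (-2.86, SE 0.11) and Tagln (-2.62, SE 0.16) were among them. Of Leydig cell genes, 5 of 10 fell, 6 adjusted over the list alone, with a median of -1.17 (camera adjusted p = 0.00121; adjusted p = 0.615 with an estimated correlation). The testosterone-forming enzyme Hsd17b3 (-4.90, SE 0.59), the nuclear receptor Nr5a1 (-4.02, SE 0.64) and the steroid hydroxylase Cyp17a1 (-1.46, SE 0.35) fell. Hsd17b3 and Nr5a1, the 2 Leydig genes at least 10-fold lower, are also known from Sertoli cells. The other probe set of Nr5a1 differed by 0.07 but lay near background in both fractions (2.83 in Thy1-positive against 2.76 in Thy1-negative cells). Cyp11a1 (-0.81) did not pass. Macrophage genes moved the other way in the same arrays, by a median of 6.10. The count of lower genes was 12, 9 and 8 without N1, N3 and P3 in the Sertoli list, 0 without both arrays numbered 3 (0 also for the Leydig list, 1 for the myoid list), and 6 without P3 in the myoid list, where 1 gene rose without P1. In the Leydig list it was 2, 2, 3, 3 and 2 without N1, N3, P1, P2 and P3. In the 6 leave-one-out fits Ptgds and Nr5a1 passed in 3 and Cyp17a1 in 1, and the count of higher Sertoli genes was 2 without N2.

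Interstitial mesenchyme and endothelial genes went both ways, while macrophage genes rose in the same arrays. Of 17 mesenchyme genes, 3 rose and 1 fell, with 3 and 1 adjusted over the list alone. Besides Thy1, the matrix genes Postn (1.96, SE 0.20) and Fbln1 (1.08, SE 0.18) rose and the transcription factor Tcf21 fell (-1.24, SE 0.31). Of 15 endothelial genes, 3 rose and 3 fell, with 3 and 3 adjusted over the list alone. The angiopoietin receptor Tek (1.28, SE 0.25), the VEGF receptor Flt1 (0.81, SE 0.08) and Ramp2 (0.77, SE 0.20) rose. Sox18 (-2.25, SE 0.41), the VEGF receptor Kdr (-1.95, SE 0.51, at low signal in Thy1-positive cells) and Robo4 (-1.55, SE 0.36) fell. Tek and Flt1 in Thy1-negative cells (3.96, SD 0.02; 2.87, SD 0.01) and Robo4 in Thy1-positive cells (2.85, SD 0.03) hardly varied near background. Neither set passed (camera adjusted p = 0.869 and 0.849; adjusted p = 0.955 with an estimated correlation for both). The mesenchyme median (0.09) and mean (0.28) were positive while the set test pointed down, and the endothelial median was 0.00 with a mean of -0.18 and a test pointing down. Without N1, N3 and P3 the count of higher endothelial genes was 1 each, and without N3, P1, P2 and P3 that of lower ones was 0. The lower mesenchyme count was 0, 0, 0, 0, 3 and 0 without N1, N2, N3, P1, P2 and P3. Postn and Flt1 passed in all 6 leave-one-out fits, Tek and Fbln1 in 3, Sox18 and Robo4 in 2, and Kdr, Ramp2 and Tcf21 in 1.

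**Figure D3:**
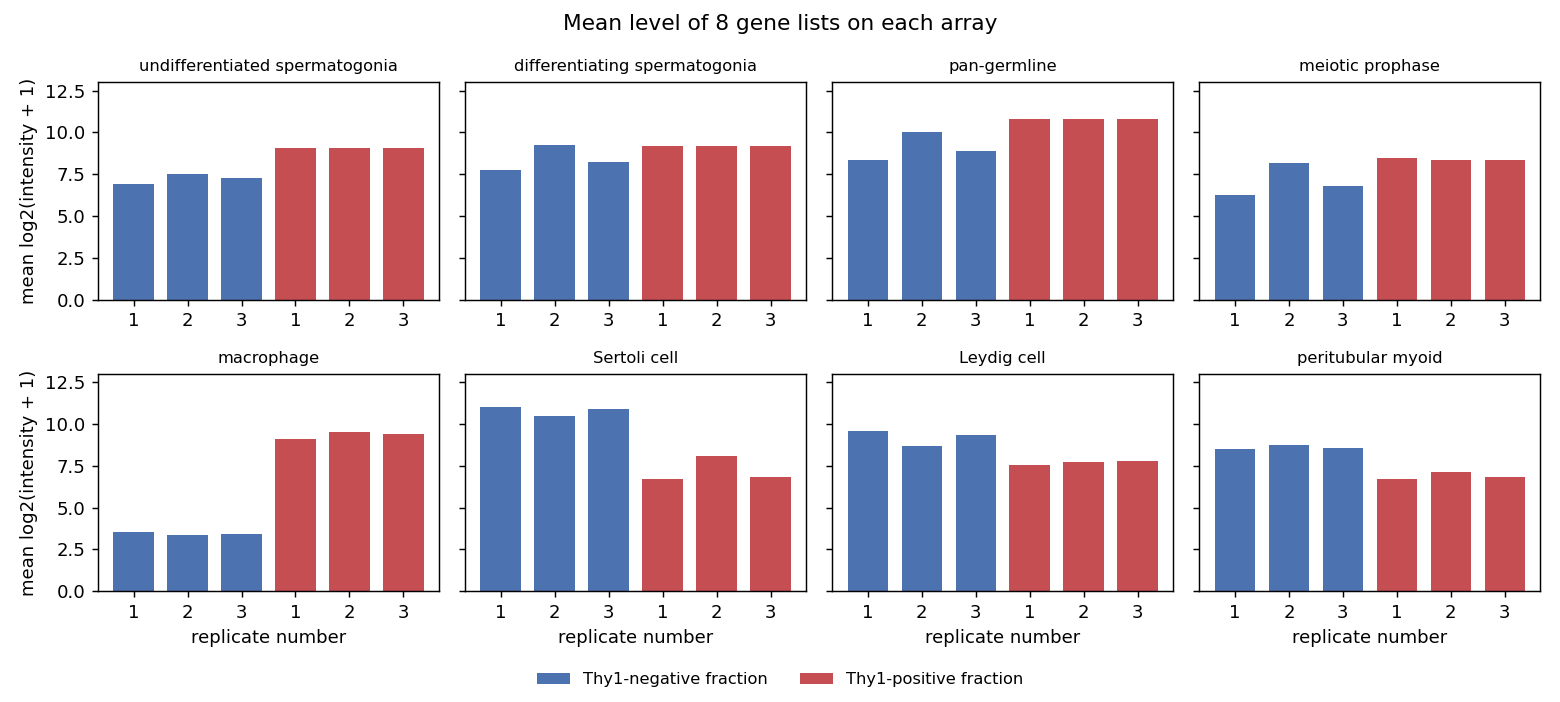
Mean log2(intensity + 1) of the measured genes of 8 lists on each of the 6 arrays, with Thy1-negative arrays in blue and Thy1-positive arrays in red. The macrophage list lies at 3.51, 3.36 and 3.40 on N1, N2 and N3 and at 9.10, 9.51 and 9.38 on P1, P2 and P3, while the meiotic list reaches 8.19 on N2 against 6.26 on N1 and 6.79 on N3.

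Of 26 ligands known or proposed to act on spermatogonia, 8 fell in Thy1-positive cells and 2 rose, also 8 and 2 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.00509; adjusted p = 0.621 with an estimated correlation and 0.0559 with arrays centred on housekeeping genes). Besides Gdnf and Edn1, the Sertoli cell hedgehog ligand Dhh fell (-4.46, SE 0.59), and Tgfb1 (2.18, SE 0.17) and Fgf9 rose. Gdnf, Kitl, Dhh, Inhbb and Fgf9 are in the Sertoli list as well. The macrophage genes rose in the same arrays. Of 35 receptors for such factors, 7 rose and 9 fell, with 7 and 9 adjusted over the list alone. By the probe set kept per gene, Csf1r, Ret and Gfra1 rose most, and the Wnt receptor Fzd1 (-2.02, SE 0.31), Kdr and the BMP receptor Bmpr2 (-1.71, SE 0.21) fell. The order of Ret and Gfra1 rests on that choice, as the other Gfra1 probe sets differed by 5.47 and 4.71. The set did not pass (camera adjusted p = 0.611; adjusted p = 0.810 with an estimated correlation), and its median (0.01) and mean (0.24) were positive while the test pointed down. The lower ligand count was 4 without P3. The higher receptor count was 4 without N3 and 4 without P3, and the lower receptor count 4, 2, 3, 5 and 2 without N1, N3, P1, P2 and P3. Fzd1 passed in 4 of the 6 leave-one-out fits and Kdr in 1.

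Integrin and cadherin genes went both ways, with 6 of 20 higher and 6 lower, also 6 and 6 adjusted over the list alone. E-cadherin, Cdh1 (3.08, SE 0.47), the collagen-binding integrin subunit Itga1 (2.37, SE 0.22) and Epcam (1.80, SE 0.48) rose. N-cadherin, Cdh2 (-2.70, SE 0.16), Itga8 (-3.26, SE 0.13) and Itgb8 (-2.44, SE 0.28) fell. The set did not pass (camera adjusted p = 0.530; adjusted p = 0.810 with an estimated correlation), and its median was 0.09 with a mean of -0.15 and a test pointing down. Basement membrane and matrix genes were lower, with 10 of 26 falling and 1 rising, or 16 and 2 adjusted over the list alone, and a median of -1.19 (camera adjusted p = 0.000220; adjusted p = 0.621 with an estimated correlation). The metalloproteinase inhibitor Timp3 (-3.57, SE 0.56), the collagen IV chain Col4a3 (-3.16, SE 0.45) and the laminin chain Lama1 (-2.91, SE 0.39) fell and the nidogen Nid2 (1.67, SE 0.08) rose, with macrophage genes moving the other way. The higher integrin and cadherin count was 3, 2, 3 and 1 without N2, N3, P2 and P3, and the lower matrix count 4, 2, 4 and 2 without N1, N3, P1 and P3. Cdh1 failed without P3 (3.03), Timp3 passed in 4 of the 6 leave-one-out fits and Epcam in 1.

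Genes of the cell cycle and DNA replication were higher, with 10 of 28 rising and 13 adjusted over the list alone, and a median of 0.49 (camera adjusted p = 0.00151; adjusted p = 0.621 with an estimated correlation and 0.0949 with arrays centred on their median). The mitotic kinesin Kif11 (1.17, SE 0.27), the replicative helicase subunit Mcm3 (0.95, SE 0.12) and the spindle checkpoint kinase Bub1b (0.84, SE 0.10) rose, beside the macrophage genes. Immediate early genes, which respond to stimulation and tissue dissociation, were lower, with 8 of 20 falling and 14 adjusted over the list alone, and a median of -1.05 (camera adjusted p = 4.39e-05; adjusted p = 0.621 with an estimated correlation). Ccn1 (-3.73, SE 0.47), the orphan nuclear receptor Nr4a1 (-1.74, SE 0.46; adjusted p = 0.0618 over all probe sets) and Btg2 (-1.72, SE 0.29) fell. The other probe sets of Kif11 differed by 0.08 and 0.60 and were not called. Without N1, N3, P1, P2 and P3 the count of higher cell cycle genes was 3, 3, 4, 18 and 3, and without N1, N3, P1 and P3 that of lower immediate early genes was 3, 5, 3 and 2. Mcm3, Bub1b and Ccn1 passed in all 6 leave-one-out fits, Btg2 in 3, Kif11 in 2 and Nr4a1 in 1.

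Metabolic genes changed in both directions. Of 18 genes of cholesterol synthesis, 7 rose and 2 fell, with 8 and 2 adjusted over the list alone and a median of 0.51 (camera adjusted p = 0.134; adjusted p = 0.621 with an estimated correlation). Mvk (1.11, SE 0.11) and Idi1 (0.99, SE 0.14) rose and Ebp (-1.91, SE 0.22) and Hmgcs1 (-0.35, SE 0.05) fell. The probe sets of Lss differed by 1.35, 0.07 and -0.78 and were called in opposite directions. Of 16 genes of glycolysis, 5 rose and 4 fell, with 6 and 6 adjusted over the list alone (camera adjusted p = 0.817; adjusted p = 0.921 with an estimated correlation). The phosphofructokinase of platelets Pfkp (3.55, SE 0.44), the aldolase Aldoc (2.04, SE 0.42) and the pyruvate kinase Pkm (0.87, SE 0.05) rose. The liver phosphofructokinase Pfkl (-2.38, SE 0.55), Tpi1 (-0.90, SE 0.23) and Pgk1 (-0.86, SE 0.19) fell. The glycolysis median (0.05) and mean (0.18) were positive while the set test pointed down. Macrophage genes rose in the same arrays as these lists. The higher cholesterol count was 4, 3, 3 and 2 without N1, N3, P1 and P3, and the lower count 1 without P3. For glycolysis the higher count was 3, 3, 3 and 2 without N1, N3, P1 and P3, and the lower count 0, 0, 0, 2 and 0 without N1, N3, P1, P2 and P3. Hmgcs1 failed without P3 (-0.34), Aldoc and Pfkl passed in 2 of the 6 leave-one-out fits, and Lss, Tpi1 and Pgk1 in 1.

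Of 24 genes of DNA methylation and chromatin, 5 rose and 2 fell, with 5 and 2 adjusted over the list alone and a median of 0.15 (camera adjusted p = 0.499; adjusted p = 0.810 with an estimated correlation). The maintenance methylation factors Uhrf1 (1.26, SE 0.16) and Dnmt1 (0.78, SE 0.19) and the arginine methyltransferase Prmt5 (1.06, SE 0.14) rose, and the dioxygenase Tet1 (-1.83, SE 0.23) and the heterochromatin gene Cbx1 (-0.84, SE 0.15) fell. The other 4 probe sets of Cbx1 were not called (0.42, 0.33, -0.06 and 0.17), and the mean of all its probe sets turned the direction (0.0052, adjusted p = 0.987). Of 18 imprinted genes, 2 rose and 3 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.849; adjusted p = 0.955 with an estimated correlation). Cdkn1c (1.73, SE 0.12) and Phlda2 (1.24, SE 0.22) rose and Nnat (-2.48, SE 0.29), Sgce (-1.57, SE 0.36) and Grb10 (-0.86, SE 0.22) fell. The median (0.04) and mean (0.03) were positive while the test pointed down. Of 11 housekeeping genes, 5 rose and 1 fell, with 6 and 1 adjusted over the list alone and a median of 0.18 (camera adjusted p = 0.391; adjusted p = 0.621 with an estimated correlation). The genes B2m, the light chain of MHC class I (1.13, SE 0.24), Hprt (0.44, SE 0.09) and Sdha (0.39, SE 0.10) rose and Pgk1 fell. None of the 4 probe sets of Sdha passed over all probe sets, and another abundant one differed by -0.39. Macrophage genes rose in the same arrays as these lists. The higher chromatin count was 3, 10, 2, 2, 2 and 3 without N1, N2, N3, P1, P2 and P3, and the lower count 1 without N1, N3 or P3. The higher imprinted count was 1 without N3, P1 or P3 and the lower count 1 without N1, N3, P1 or P3. The higher housekeeping count was 0, 0, 1, 1 and 0 without N1, N3, P1, P2 and P3, with Pgk1 not called there. Among the 6 leave-one-out fits Cbx1 and Phlda2 passed in 3, Hprt and Sgce in 2, and Dnmt1, Grb10, B2m, Sdha and Pgk1 in 1.

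Set tests passed for 7 lists higher and 6 lower of 25 by camera with a preset correlation, and for 0 with an estimated correlation, where adjusted p ran from 0.356 to 0.955 and 3 lists had an unadjusted p below 0.05. Even the macrophage list, with all 21 genes called, had an unadjusted camera p of 0.0142 there. Failing with an estimated correlation therefore does not show that a list is unchanged. By fry, which asks only whether a list's genes move, on balance, one way, 15 lists passed.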

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

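The control probe sets were compared without a test, and the value of pyruvate carboxylase was looked at only after the main comparison had been seen.

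In control probe sets that the comparison of the fractions does not use, the poly-A RNA added before labelling gave a signal 0.78 log2 units higher in Thy1-positive than in Thy1-negative arrays over 12 probe sets (7.35 ± 0.34 against 6.57 ± 0.24, SD, n = 3), while 9 probe sets for hybridisation controls differed by -0.04.

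The 4 control probe sets for pyruvate carboxylase, also outside that comparison, were 1.02 log2 units higher in Thy1-positive arrays (6.71 ± 0.08 against 5.69 ± 0.23, SD, n = 3).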

How the results depend on the processing

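Of the settings below, leaving out both arrays numbered 2 or both numbered 3, and the check of whether equal numbers pair the arrays, were chosen only after the results were seen.

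Under quantile normalization, raised low values, a pseudocount of 16 and the replicate block, all 25 lists kept their direction and their side of the threshold, and the macrophage list passed under every setting except an estimated correlation. Of 116 called named genes, 67 passed in all 6 fits that left out 1 array; without N1, N2, N3, P1, P2 and P3, 33, 3, 44, 36, 24 and 49 of the 119 named genes lost their call, and leaving out an array also leaves fewer samples to test. With both arrays numbered 3 left out, 102 lost it, and under quantile normalization, housekeeping centring and a pseudocount of 16, 3, 3 and 4 did. Signal over background limits genes near the floor: raising the pseudocount to 16 left 72 probe sets at 10-fold or more higher and 192 lower, since it shrinks folds of low values. For the other changes below the cause was not tested.

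Counts of probe sets changed as follows. Centring on the median gave 25863 higher probe sets, and array weights, whose estimation did not reach its tolerance, 13345 higher and 10596 lower. With the replicate number as a block, 746 were higher, 485 lower and 49 at least 10-fold lower, and 79 of the 119 named genes lost their call; the arrays are not known to be paired, and the residuals of equal numbers correlated at -0.19, -0.17 and -0.01 across probe sets, which are not independent replicates, with 0 of 6 arrays closest to their own number. Leaving out both arrays numbered 2 gave 568 at least 10-fold lower. Leaving out both numbered 3 gave 219 higher and 144 lower, with 79 and 14 at 10-fold or more. Over the fits without 1 array, the higher count ranged from 1639 to 6790, the lower from 1538 to 6214 and the count at least 10-fold lower from 159 to 449; the count at least 10-fold higher, 177 to 239, stayed within 1.5 times.

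Adjusted p of the lists changed as follows. Centring on the median left 4 lists higher and gave 0.350 for meiotic prophase, 0.190 for GDNF-responsive, 0.0949 for cell cycle and 0.953, with the direction turned, for chromatin. Centring on the housekeeping list brought differentiating spermatogonia (0.0190), pluripotency (0.00869) and cholesterol (0.0205) past the threshold, took niche ligands (0.0559) out and turned the direction of mesenchyme (0.351), endothelium (0.848), receptors (0.536), integrins and cadherins (0.848), glycolysis (0.570) and imprinted genes (0.706). The housekeeping list used for centring had a mean difference of 0.13 itself. It holds B2m of MHC class I (1.13) and Pgk1 (-0.86), which differed between the fractions, so this scaling depends on them. Among probe sets above the median, where 23 lists kept enough genes, pluripotency passed (0.0317) and mesenchyme and endothelium (both 0.941) turned. The intensity trend gave 0.0485 for erythroid genes and array weights 0.0973 for GDNF-responsive genes. Without probe sets ending in _x_at or _s_at glycolysis turned (0.898), as did receptors and glycolysis (both 0.857) with the mean of all probe sets. An estimated correlation left 0 lists higher and 0 lower: 0.356 for macrophage, 0.385 for undifferentiated spermatogonia and T lymphocyte, 0.426 for myoid, 0.459 for Sertoli, 0.615 for GDNF-responsive and Leydig, 0.621 for pan-germline, ligands, matrix, cell cycle and immediate early genes, and 0.763 for meiotic prophase. Leaving out both arrays numbered 2 gave 0.0647 for GDNF-responsive genes, and leaving out both numbered 3 gave 0.0587 for meiotic prophase and turned mesenchyme (0.845) and imprinted genes (0.945). Without 1 array the range was 0.0195 to 0.407 for differentiating spermatogonia, 2.04e-05 to 0.0745 for meiotic prophase, 0.00293 to 0.0767 for GDNF-responsive, 0.0171 to 0.117 for erythroid, 0.316 to 0.991 for mesenchyme, 0.518 to 0.944 for endothelium and 0.389 to 0.974 for imprinted genes. In those fits 1 list each lost its call without N2, N3 and P2, and 2 gained it without N2. Without N1, N3, P1 and P2, 2, 1, 2 and 1 lists turned direction, none of them past the threshold.

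Over all settings, adjusted p ran from 9.09e-10 to 0.385 for undifferentiated spermatogonia, 0.0190 to 0.810 for differentiating, 2.90e-08 to 0.621 for pan-germline, 2.04e-05 to 0.763 for meiotic, 0.000355 to 0.615 for GDNF-responsive and 0.00869 to 0.459 for pluripotency genes. For cell types it ran from 6.12e-13 to 0.459 for Sertoli, 0.000186 to 0.615 for Leydig, 7.11e-09 to 0.426 for myoid, 0.149 to 0.991 for mesenchyme, 0.518 to 0.955 for endothelium, 4.16e-25 to 0.356 for macrophage, 0.000822 to 0.385 for T lymphocyte and 0.0171 to 0.621 for erythroid. It ran from 0.112 to 0.961 for receptors, 0.000126 to 0.621 for ligands, 0.0944 to 0.848 for integrins, 9.47e-07 to 0.621 for matrix, 6.64e-06 to 0.621 for cell cycle, 0.0205 to 0.621 for cholesterol, 0.294 to 0.959 for glycolysis, 0.114 to 0.953 for chromatin, 0.149 to 0.974 for imprinted and 2.65e-07 to 0.621 for immediate early genes.

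Of single genes, Lss reversed to -0.78 without probe sets ending in _x_at or _s_at, which remove its most abundant probe set, and Cbx1 to 0.0052 (adjusted p = 0.987) with the mean of all its probe sets.

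Splitting the 6 arrays into 3 and 3 allows 10 splits, too few for a share below 0.05. The real split called 10533 probe sets, against at most 1 in another split, 554 at 10-fold or more against 0, and 5996 genes against 0, each matched by 1 split, the real one. It called 13 lists against 15 in the highest other split, which grouped N1, N3 and P2, and 3 splits called as many.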

Other observations

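The 4 lists of the first paragraphs were written, and all tests of the last paragraphs chosen, only after the results had been seen. The set-test p values of these 4 lists come from the values that prompted the lists, so they carry no weight as evidence. They cannot be set against those of the 25 lists fixed beforehand. Nr5a1 and Hsd17b3 are in both the hormone list and the Leydig list.

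Genes of further blood cell types were higher in Thy1-positive cells. Of 11 genes of cytotoxic lymphocytes, 7 rose, with a median difference of 3.47 (camera adjusted p over these 4 lists = 1.22e-05; adjusted p = 0.0322 with an estimated correlation): the granzymes Gzmc (6.33, SE 0.69) and Gzma (4.85, SE 0.04), the protease Ctsw (4.63, SE 0.12) and the NK cell receptor Klrd1 (4.28, SE 0.06), all at low signal in Thy1-negative cells, were among them. Of 10 mast cell genes, 7 rose, with a median of 1.19 (camera adjusted p = 0.000414; adjusted p = 0.113 with an estimated correlation), including carboxypeptidase Cpa3 (6.36, SE 0.26, at low signal in Thy1-negative cells) and the chymases Cma1 (5.32, SE 0.26) and Mcpt4 (5.00, SE 0.21, from 2.78). Of 13 genes of MHC class I and II, 10 rose, with a median of 2.43 (camera adjusted p = 2.63e-05; adjusted p = 0.0944 with an estimated correlation), among them H2-D1 of class I (3.56, SE 0.32) and Cd74 (5.14, SE 0.23, at low signal in Thy1-negative cells) and H2-Eb1 (3.38, SE 0.12) of class II. Without both arrays numbered 3 the counts were 3, 2 and 2 for the cytotoxic, mast cell and MHC lists, and with the replicate block 7, 5 and 5. Macrophages carry both classes, and the macrophage list rose in the same arrays by a median of 6.10.

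Of genes related to hormones in Sertoli and granulosa cells, 6 of 6 were lower in Thy1-positive cells, by a median of -4.83 (camera adjusted p = 6.33e-05; adjusted p = 0.113 with an estimated correlation). The androgen-binding protein gene Shbg (-5.00, SE 0.74), the nuclear receptor Nr0b1 (-4.93, SE 1.03), the estradiol-forming enzyme Hsd17b1 (-4.77, SE 0.63) and the AMH receptor Amhr2 (-4.46, SE 0.70) were among them. Without N1, N3 and P3 the count was 4, 3 and 3, and it was 0 with the replicate block and 0 with both arrays numbered 3 left out but 6 under median centring, housekeeping centring and quantile normalization.

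Csf1r was higher in Thy1-positive cells, where it may mark either stem cells or macrophages. Against a lower share of Sertoli cells as the whole cause, which would raise all other cell types alike, the other macrophage genes exceeded the higher of the endothelial (0.00) and mesenchyme (0.09) medians by 6.09, more than the summed spread of 3.48. The 20 macrophage genes besides Csf1r all rose, with a median of 6.18, so RNA of macrophage genes was enriched in the Thy1-positive fraction. Lyz2, C1qb and Mrc1 measured 12.04, 11.25 and 11.17 there, against 4.88, 3.54 and 5.17 in Thy1-negative cells. These levels come from different probe sets and do not compare abundance between genes. Whether macrophage RNA accounts for the rise of Csf1r stays open, and how such cells would pass the sort was not tested. Of the 21 listed genes 1, Csf1r itself, is in another list chosen beforehand, and 6 were at low signal in Thy1-negative cells. The others are not thereby shown to be expressed there. The list's mean was 3.42, and Tyrobp (3.03), Fcer1g (3.11) and Ctss (3.19), for example, lay near background. Expression by the germ cells themselves cannot be told apart with 3 arrays: from P1 to P2 the Csf1r probe sets differed by 0.51 on average, against a median of -0.25 for 20 called spermatogonia genes (16 of 20 below 0) and 0.38 for the macrophage genes (16 of 20 above 0).

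N2 lay nearer to the Thy1-positive arrays than N1 and N3 did. Against a carry-over of Thy1-positive cells of every kind, the germ cell genes would put their share at 50.6%, but all 21 macrophage genes lay below the level this share predicts, at a median of -5.17 relative to it (spread 1.98). Against a carry-over of Thy1-positive germ cells alone, in the proportions found there, all 7 GDNF-responsive genes that differ by more than 1 lay below the prediction, at a median of -2.06 (spread 0.80), a list taken after the undifferentiated genes had not decided it (-1.12, spread 1.38, 20 of 24 below; 5 genes shared). Differentiating genes (-0.08, spread 0.38, 4 of 7 below) and meiotic genes (0.28, spread 0.31, 3 of 15 below) lay within their spread of the prediction. A larger share of germ cells past the undifferentiated stage may contribute: meiotic genes exceeded N1 and N3 by a median of 1.76, differentiating genes by 1.28 and all 30 undifferentiated genes by 0.45 (spread 1.00), a gap of 1.31 between meiotic and undifferentiated genes (permutation of genes, which are not independent replicates, p = 5e-05). Carry-over of only a part of the germ cells, a difference in donor age and a difference in the sort stay open, as untested.

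The arrays numbered 3 lay between the other arrays of their fraction in 88.1% of 2889 probe sets for N3 and 90.1% of 2169 for P3, against 27.9% to 40.2% for the others. A pool of RNA of the other preparations would place every gene group alike. Over 10 lists, however, the median position of P3 between P1 and P2 ran from 4.17% for Sertoli genes to 60.3% for immediate early genes (spread 21.1%, permutation of genes, p for the range = 0.00025). Genes are not independent replicates, so the permutation p values here do not measure variation between preparations. For N3 positions decided nothing: over 18 lists they ranged by 76.2% (spread 88.9%, permutation p = 0.00765), and Sertoli genes differed from pan-germline genes by 13.2% (spread 14.7%) and from matrix genes by 5.10% (spread 14.8%, permutation p = 0.507). N3 exceeded both N1 and N2 in 18 of 20 immediate early genes, by a median of 0.47 over the list (spread 0.41, permutation p for the largest of 25 lists = 0.0005). A pool of their RNA would stay below the higher one. As these genes respond to dissociation, the list cannot decide about a pool of cells handled apart. No biological explanation was tested, and chance in the composition of the preparations stays open.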
